A study of Mus musculus with 4 samples.

How the data were processed

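Single-cell RNA was measured with droplet-based 10x Genomics 3' chemistry (v3.1) in 4 libraries of mouse muscle cells, 1 per group (fiSC, ASC, myoblast and MPC), and sequenced on an Illumina NovaSeq instrument. The deposited files are raw UMI counts per gene and cell barcode, with no normalization. Per the submitters' processing notes the reads were aligned with STAR 2.7.10b to GRCm39. How UMIs were collapsed, how barcodes were called as cells and which gene annotation was used are not stated there. The files list 25828 features under 25804 distinct symbols, with Ensembl gene identifiers and an EGFP sequence, and counts of the 22 symbols on more than 1 feature were summed. The files carry no coordinates, and the reference at hand is of another build than GRCm39, so genes are given by symbol and identifier only.

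The deposited barcodes numbered 2705 for fiSC, 10818 for ASC, 2993 for myoblast and 11847 for MPC, with 21434933, 199488336, 60415378 and 171748476 UMIs. Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs. Under 1000 UMIs lay 9.57% of the fiSC, 28.1% of the ASC, 5.65% of the myoblast and 9.89% of the MPC barcodes, and 16.0, 10.1, 15.6 and 13.1% had more than 10% mitochondrial UMIs. The filter kept 2251, 6743, 2412 and 9895 cells. Doublets were scored with Scrublet (in scanpy 1.11.5) at an expected rate of 0.8% per 1000 cells. Its automatic threshold was used where it marked at least 0.5% of cells, which held for ASC (4.37%) and not for fiSC (0.222%), myoblast (0.290%) or MPC (0.0101%), where the cells scoring at or above the quantile set by the expected rate were removed, a rule set after the automatic thresholds were seen. This removed 66, 295, 61 and 836 cells. With tied scores included, the last rule took 2.93% of fiSC, 2.53% of myoblast and 8.45% of MPC cells, above the expected 1.80, 1.93 and 7.92%. The retained cells had median mitochondrial shares of 3.38, 2.25, 5.89 and 3.87% and median gene counts of 2543, 4132.5, 5149 and 3895.

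Each library was clustered by itself: log-normalized counts, 2000 variable genes without the myogenic and cell cycle genes of the lists, mitochondrial genes and EGFP, 30 components, 15 neighbours and Leiden clustering at resolution 0.5 (igraph 0.11.9, scikit-learn 1.9.0). Clusters were named "-like" from 14 marker lists (myogenic progenitor, differentiating myocyte, mature myofibre, fibroblast, tenocyte, endothelial, mural, macrophage, neutrophil, T or NK cell, B cell, Schwann, erythroid and adipocyte). A name needed at least 3 detected markers, and the differentiating myocyte and mature myofibre names were joined as muscle differentiation-like. The details of naming were set after seeing the data. Leading genes were the top 10 by fold with at least 50 CPM and found in at least 10% of the cluster's cells, and markers counted from 20 CPM. A leading marker was left out where its share of the cluster's cells was under 2 times that of the other cells. Clusters stayed unnamed with median UMIs far below the library's and no leading marker of their own, or with more leading markers of another class.

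UMIs were summed over all retained cells of a library and over its progenitor-like cells, and scaled to CPM (the same total for each library). Log2 ratios carry a pseudocount of 5 CPM. A gene met the size rule at a ratio of at least 2-fold with at least 10 CPM in the higher library. With 1 library per group no test was run and no p-value is given, since cells are not replicates. Sums have exact Poisson intervals and shares of cells exact binomial (Clopper-Pearson) intervals at 95%, which cover counting error only. A count of 0 was compared with a floor of 3 counts, for sums and for shares of cells, which for sums is 0.150 CPM in fiSC, 0.0167 in ASC, 0.0550 in myoblast and 0.0223 in MPC. For genes at 10 CPM or more the Poisson half-width was at most 14.9, 4.74, 8.75 and 5.49% in that order. When 1 library's cells were split at random into equal parts, 37 genes met the size rule in fiSC, 1 in ASC, 0 in myoblast and 0 in MPC.

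The 20 gene lists cover satellite cell quiescence, myogenic transcription factors, Notch pathway, Wnt/beta-catenin targets, TGF-beta targets, cAMP/CREB targets, immediate early and heat shock, G2/M cell cycle, DNA replication, p53 and cell cycle inhibitors, early muscle differentiation, mature fibre genes, extracellular matrix, imprinted growth genes, glycolysis, oxidative phosphorylation, cholesterol synthesis, hypoxia, interferon response and ribosomal proteins. A member was measured when it had at least 10 CPM in the higher library. The median log2 ratio of a list was placed among 10000 random lists of its size matched in 20 bins of expression, and its interval came from 200 Poisson draws of the counts. Named genes were chosen by rule: per comparison the 10 highest and 10 lowest log2 ratios among genes with at least 50 CPM in the higher library that met the size rule in the same direction in all and in progenitor-like cells, up to 4 members per list with the highest mean CPM that met the size rule in the direction of most members, and 16 genes fixed in advance, of which 1 is not reported here. The rule left out mitochondrial, ribosomal protein, haemoglobin, histone, Y-linked and unnamed predicted genes. For myoblast against ASC the rule gives counts alone.

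Shares of cells with a UMI were taken after thinning cells with at least 2000 UMIs to 2000 UMIs, which left out 50, 641, 76 and 207 cells. A cell counted as cycling with at least 2 UMIs of the G2/M list. Correlations used genes with at least 10 CPM in 1 library. For the position of MPC, genes at least 4-fold apart between a random part of the myoblast cells (equal in size to the rest) and fiSC or ASC were followed in MPC against the remaining myoblast cells, and the values without any effect came from 20 Poisson draws. The comparisons, lists, fixed genes, filters and most alternative settings were written before the data were examined. Alternatives covered TMM factors (edgeR 4.0.16, R 4.3.3; factors 1.02, 0.853, 1.04 and 1.10), pseudocounts of 1 and 20, no minimum and a minimum of 50 CPM, doublets kept, all deposited barcodes, a strict cell filter (3000 UMIs, 1500 genes, 5% mitochondrial), mitochondrial and ribosomal genes left out, means over cells, thinned cells, other resolutions (0.2 and 1.0), all variable genes, joint clustering and other thinning depths (5000 UMIs and none). Sets without macrophage-like cells, all myogenic clusters, progenitor-like cells with MPC cluster 7, and progenitor-like cells with TMM factors were added after seeing the data.

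The size rule was tested on simulated data: in each comparison 50 of 50 genes changed 3-fold were called, as were 50 of 50 at 4-fold and 50 of 50 at 8-fold, with 0 of 50 at 1.5-fold and 0 unchanged genes. The simulated counts held Poisson counting error and no spread between libraries. They therefore say nothing about false calls from differences between animals or batches. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.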

Results

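The series held single-cell RNA sequencing of mouse muscle cells in 4 groups, with 1 library per group and therefore no replicates. All cells carried a Pax7-nGFP reporter, in which nuclear GFP is made from the promoter of Pax7, the transcription factor that marks muscle stem cells (satellite cells). Freshly isolated satellite cells (fiSC) were GFP-positive cells sorted from limb muscles pooled from 3 mice aged 13 weeks. Activated satellite cells (ASC) were GFP-positive cells sorted from 17 tibialis anterior muscles 3 days after cardiotoxin injury. The mice were male and female and aged 18 to 24 weeks. Myoblasts were grown for 2 passages. The myogenic progenitor cells (MPC) were grown for 2 passages as myoblasts and then for 5 passages in a medium with Forskolin (which raises cAMP), Repsox (an inhibitor of the TGF-beta receptor) and a CHIR compound that inhibits GSK3 and so activates Wnt signalling. Each culture came from a male mouse aged 16 weeks, and the cultured cells were not sorted. The retained cells numbered 2185 for fiSC, 6448 for ASC, 2351 for myoblast and 9059 for MPC. They held 19975483, 179109303, 54581416 and 134273031 UMIs (counted molecules) in that order, and the median cell held 8760, 19810.5, 22843 and 13210 UMIs. Levels are CPM, the UMIs of a gene summed over a library's cells and scaled to the same total in each library, unless progenitor-like cells are named. Exact Poisson intervals cover counting error only, and for genes at 50 CPM or more their half-width was at most 6.40% in fiSC, 2.09% in ASC, 3.82% in myoblast and 2.42% in MPC. A gene met the size rule when the ratio of CPM plus 5 was at least 2-fold and the higher library had at least 10 CPM. Library, animals, batch and group cannot be told apart in this design.

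Cells of each library were clustered separately and clusters were named by the marker list they expressed. Myogenic progenitor-like clusters held 97.3% of fiSC cells (exact binomial interval 96.5 to 97.9%), 32.0% of ASC cells (30.9 to 33.2%), 73.9% of myoblast cells (72.1 to 75.7%) and 48.1% of MPC cells (47.1 to 49.1%). Macrophage-like clusters held 46.9% of ASC cells (45.7 to 48.2%), although this library came from a GFP sort. That share was 33.5% at clustering resolution 1.0, 32.9% with doublets kept and 28.8% with all variable genes, and 47.8% at resolution 0.2 and 48.1% in joint clustering. Where it fell, the unnamed share of ASC rose from 10.96% to 24.7, 27.2 and 29.0% in that order. In the main clustering the unnamed ASC cluster 2 (96 cells) had all 14 macrophage markers, at a sum of 37222 CPM. Muscle differentiation-like clusters held 9.18% of ASC, 13.1% of myoblast and 30.5% of MPC cells (29.5 to 31.4%), and none of the fiSC clusters. The ASC class was a single cluster with Myog at 63.3 CPM, 84.4% of its cells cycling by the G2/M count and summed differentiation markers of 1341 CPM (29491 and 81551 in the myoblast clusters), and its share was 0% at resolution 0.2 and 0.0155% (1 cell) in joint clustering. Fibroblast-like clusters held 2.75% of fiSC (60 cells), 0.186% of ASC, 1.36% of myoblast and 9.73% of MPC cells. The MPC share was 7.37% at resolution 0.2, 4.19% at 1.0, 4.22% with all variable genes, 4.95% with doublets kept and 7.06% in joint clustering. For the other libraries joint clustering gave 1.65% of fiSC, 3.33% of ASC (215 cells) and 0% of myoblast cells. Joint clustering of the libraries named 0% of myoblast and 10.1% of MPC cells as progenitor-like. Endothelial-like cells made up 0.713% of ASC, but 0.356% with doublets kept and 0% at resolution 0.2 and in joint clustering. No cluster was named from the tenocyte, mural, neutrophil, T or NK cell, B cell, Schwann, erythroid or adipocyte markers. Clusters without a name held 10.96% of ASC cells (median 1201 UMIs), 11.6% of myoblast cells (median 3259 UMIs) and 11.7% of MPC cells. Most of the last group was MPC cluster 7, which held 10.7% of the library and 1256 CPM of Pax7, and which was kept out of the progenitor-like cells. The unnamed share of MPC was 12.9% at resolution 0.2, 32.3% at 1.0, 17.2% with all variable genes, 19.3% with doublets kept and 54.4% in joint clustering. Progenitor-like comparisons rest on fiSC clusters 1 to 4, ASC clusters 3, 4, 9 and 10, myoblast clusters 1, 3, 5, 6 and 8, and MPC clusters 1 and 3.

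**Figure D1:**
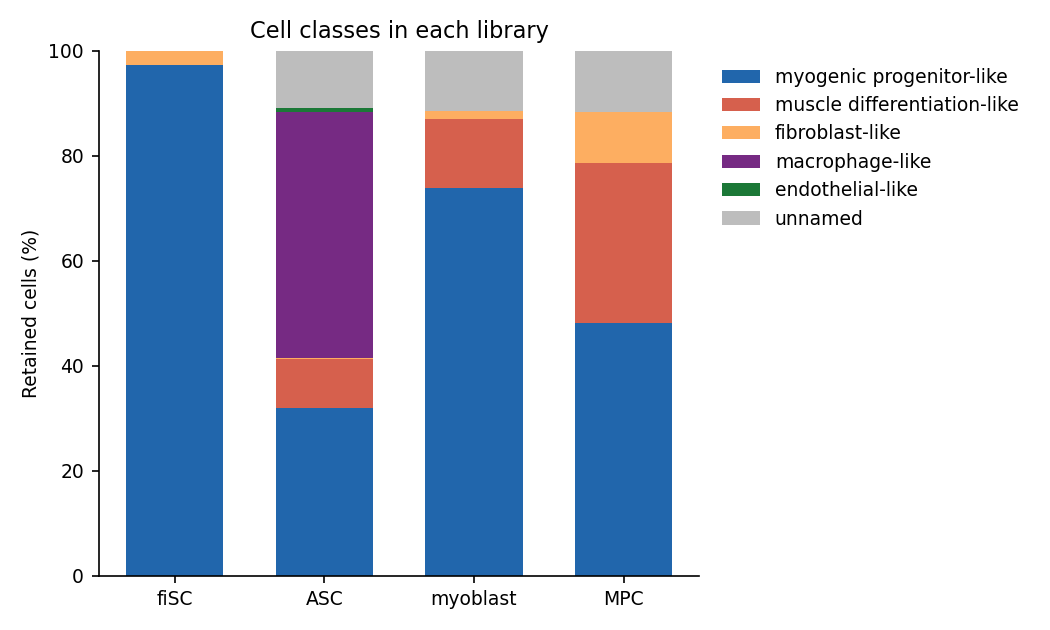
Share of retained cells (percent, axis from 0) in each cell class of the 4 libraries, drawn as stacked bars without intervals. Progenitor-like cells were 97.3% of fiSC and 32.0% of ASC, where macrophage-like cells were 46.9%, and muscle differentiation-like cells were 30.5% of MPC.

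Pax7 (ENSMUSG00000028736) stood at 835 CPM in fiSC (interval 823 to 848), 88.0 in ASC (86.6 to 89.4), 1116 in myoblast (1107 to 1125) and 669.7 in MPC (665 to 674). In progenitor-like cells it was 840.4, 119.8, 1361 and 919 CPM in that order. Myf5, which marks committed satellite cells, was at 388 CPM in fiSC against 25.9, 20.6 and 46.6 in ASC, myoblast and MPC. Myod1, the determination factor of myoblasts, was at 472, 138, 439 and 107 CPM, and within progenitor-like cells at 494, 185, 452 and 58.0. Myog (ENSMUSG00000026459), which drives terminal differentiation, was at 4.05 CPM in fiSC, 19.03 in ASC, 216 in myoblast and 359 in MPC, and in progenitor-like cells at 0.421, 13.5, 21.3 and 37.6. Calcr (ENSMUSG00000023964), a receptor of quiescent satellite cells, was at 364 CPM in fiSC, 1.09 in ASC and 0.223 in MPC (30 UMIs, interval 0.151 to 0.319). In myoblast it had 3 UMIs (0.0550 CPM, interval 0.0113 to 0.161). Cd34 was at 61.5 CPM in fiSC against 9.41, 6.74 and 0.290, and the adhesion receptor Vcam1 at 629 against 98.6, 49.7 and 24.7. Spry1, a brake on growth factor signalling, was at 193, 7.99, 9.38 and 36.4 CPM. The Notch target Hey1 (41.2, 3.95, 1.39 and 31.0 CPM) and its relative Heyl (59.5, 2.37, 3.28 and 64.4 CPM) had levels in MPC within 2-fold of fiSC. The cell cycle inhibitor Cdkn1c (ENSMUSG00000037664) was at 37.5, 25.3, 22.3 and 2366 CPM. The differentiation factor Myf6 was below 10 CPM in each library, as was Axin2, a feedback gene of Wnt signalling (3.45, 7.12, 0.623 and 6.70 CPM). Nr4a1, a rapid cAMP target, was at 195, 19.02, 8.23 and 12.2 CPM.

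Shares of cells with a UMI were compared after each cell was thinned to 2000 UMIs. Pax7 was seen in 63.4% of fiSC cells, 11.5% of ASC, 75.5% of myoblast and 59.8% of MPC, and without thinning in 88.0, 42.5, 88.0 and 84.7%. In ASC it was seen in 24.2% of progenitor-like cells (median depth before thinning 46826 UMIs) and in 0.963% of macrophage-like cells (29 of 3010, median 15936.5 UMIs), which should lack it. Calcr was seen in 27.4% of fiSC cells, in 0.0452% of MPC cells and in 0 of 2275 myoblast cells, which allows up to 0.132% of cells with a UMI at that depth (3 counts of the total). Without thinning those shares were 50.7, 0.287 and 0.0851%. The ASC share for Calcr, 0.293%, compares with 0.0332% of macrophage-like cells. The proliferation marker Mki67 was at 8.46 CPM in fiSC, 158 in ASC, 156.5 in myoblast and 286 in MPC. Cells with at least 2 UMIs of the G2/M list among 2000 were 0.890% of fiSC (interval 0.537 to 1.39%), 43.6% of ASC (42.3 to 44.9%), 44.7% of myoblast (42.7 to 46.8%) and 57.7% of MPC (56.7 to 58.8%). Among progenitor-like cells these shares were 0.432, 86.2, 54.7 and 67.0%, against 6.58% of the macrophage-like cells of ASC. Without thinning the shares of all cells were 5.13, 77.5, 75.3 and 80.3%, and the summed G2/M genes stood at 56.9, 1949.7, 1951 and 3059 CPM.

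**Figure D2:**
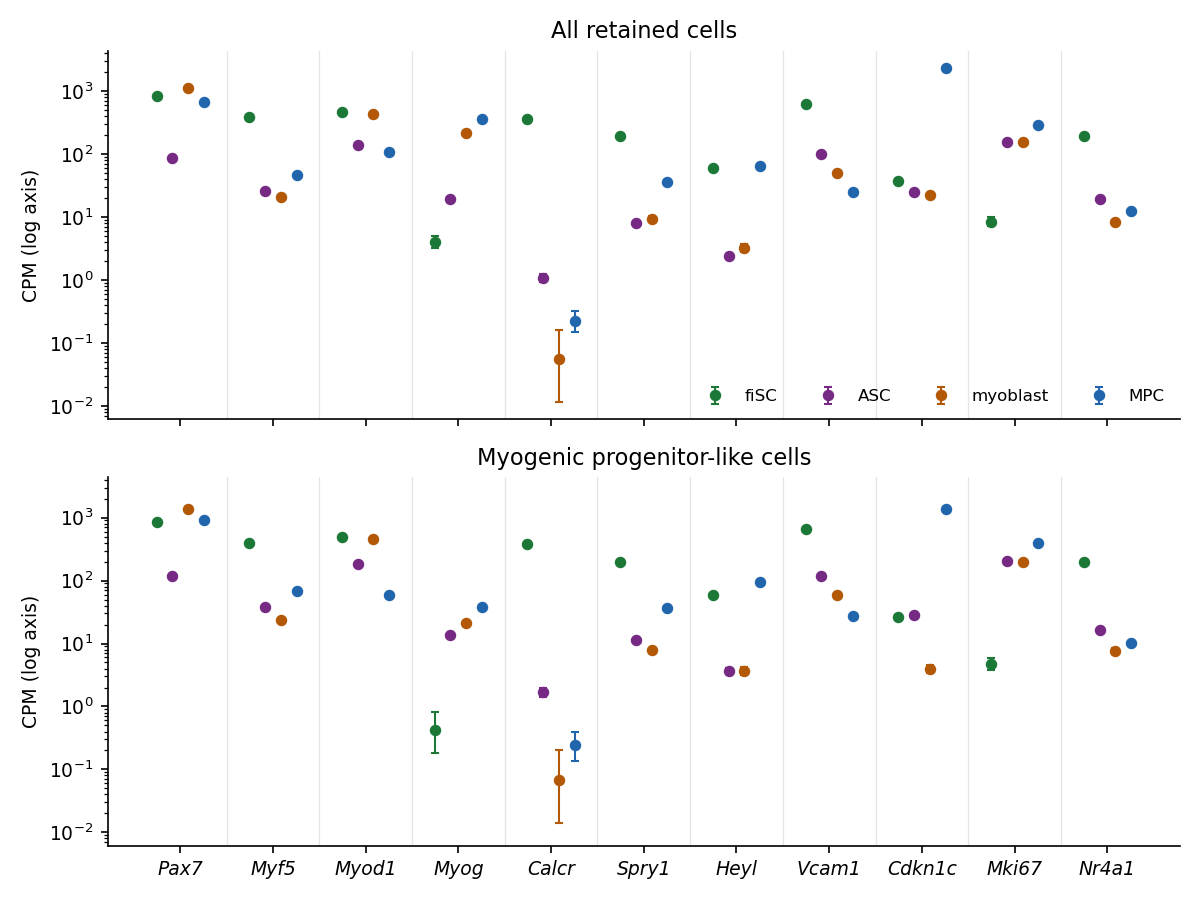
Levels (CPM, log axis) of genes fixed in advance in all retained cells (upper panel) and in progenitor-like cells (lower panel) of the 4 libraries, with exact 95% Poisson intervals for counting error. In all cells Pax7 ranged from 88.0 in ASC to 1116 in myoblast, and Cdkn1c from 22.3 in myoblast to 2366 in MPC.

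MPC against myoblast addresses what differed after the small molecule medium. Most measured members of the satellite cell quiescence, Notch pathway and hypoxia lists were higher in MPC, and most of the TGF-beta and p53 lists were lower. Of 15 measured quiescence genes, 11 were higher and 1 lower, with a median log2 ratio of 2.00, and in progenitor-like cells the same counts held with a median of 2.26 (interval 2.19 to 2.33). Cdkn1c was 106-fold higher (1384 against 3.97 CPM in progenitor-like cells), the growth arrest gene Gas1 was at 312 against 45.5 CPM, and the receptor Notch3 was 3.62-fold higher. These examples were chosen among members in the direction of most. In the muscle differentiation-like cells of MPC Cdkn1c was at 5191 CPM. Pax7 (669.7 against 1116 CPM) and Vcam1 (24.7 against 49.7 CPM) were not higher in MPC, and neither met the size rule. Cd34 (0.290 against 6.74 CPM) and Calcr (0.223 against 0.0550 CPM) were too low to count as measured. The median therefore does not speak for each quiescence marker. Of 9 Notch genes 6 were higher and 0 lower (median 1.71, progenitor-like 1.88), among them Heyl (19.6-fold), Notch1 (128 against 35.7 CPM) and Dtx4 (76.8 against 16.4 CPM). As a description of these libraries, the quiescence, Notch and hypoxia medians were above 100% of 10000 random lists matched on expression, in all and in progenitor-like cells. The quiescence list shares 3 genes with the Notch list and 9 of its 20 with the progenitor markers that named the clusters.

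All but 1 of the 10 hypoxia genes were higher in MPC (median 2.25, progenitor-like 2.31), with Bnip3, a mitophagy gene, 9.72-fold and the oxidase Ero1a 6.18-fold higher. Of 14 glycolysis genes 7 were higher (median 1.08, progenitor-like 0.97), including Pgk1 (2.79-fold) and Tpi1 (3.50-fold). Among imprinted growth genes 5 of 11 were higher and 1 lower (median 0.86, progenitor-like 1.12), with Grb10, an adaptor that restrains insulin signalling, at 710.5 against 101 CPM. Of 19 extracellular matrix genes 5 were higher and 4 lower (median 0.58, progenitor-like 0.72), and the collagen VI gene Col6a1 was 35.2-fold higher, with fibroblast-like cells at 9.73% of MPC (4.19 to 7.37% in the other clusterings) and 1.36% of myoblast. Immediate early and heat shock genes were higher for 6 of 16 and lower for 1 (median 0.77, progenitor-like 1.14), with Fos 10.1-fold higher. Of 6 Wnt targets 3 were higher and 1 lower (median 0.99), but 2 and 2 of 5 in progenitor-like cells (median 0.90). Nkd1, a feedback inhibitor of Wnt signalling, was at 11.9 against 1.23 CPM.

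Of 10 TGF-beta targets 8 were lower in MPC and 1 higher (median -1.93, progenitor-like -1.76), with Thbs1 21.3-fold and the feedback gene Pmepa1 9.87-fold lower. Of 9 p53 targets and cell cycle inhibitors 7 were lower and 0 higher (median -1.29, progenitor-like -1.86), and Cdkn2a, which encodes p16 and p19, was 7.30-fold lower. MPC cluster 7, outside the progenitor-like cells, had Cdkn2a at 201 CPM, and with it the progenitor-like median of the list was -1.32. Of 12 cAMP/CREB targets 4 were higher and 2 lower (median 0.01, progenitor-like -0.12), with the phosphodiesterase Pde4b 12.4-fold higher. Early differentiation genes were higher for 2 of 21 and lower for 4 (median -0.55, progenitor-like -0.47), with the acetylcholine receptor gene Chrna1 at 68.9 against 602 CPM. Mature fibre genes were higher for 1 of 14 and lower for 5 (median -0.42), and in progenitor-like cells the median turned to 0.47. Of 20 G2/M genes 2 were higher (median 0.46), and 0 of 19 DNA replication genes met the size rule (median 0.32). Myogenic transcription factors had 3 higher and 2 lower of 13 (median 0.15), and Eya1, a cofactor of progenitor genes, was at 109.9 against 26.0 CPM. Oxidative phosphorylation (median 0.09), cholesterol synthesis (0.12) and ribosomal protein genes (0.37) had at most 1 member past the size rule, and 1 of 3 interferon genes was lower (median -0.18). The cholesterol median was -0.04 and that of cAMP/CREB targets -0.12 in progenitor-like cells, so neither list has a steady sign.

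By the size rule 647 genes were higher and 608 lower in MPC than in myoblast, and 740 and 803 in progenitor-like cells. TMM factors gave 558 and 657 (45.9% higher in place of 51.6%) and the strict cell filter 650 and 880 (42.5%), so which direction holds more genes is not settled. The main and progenitor-like counts shared 566 higher and 559 lower genes. The genes with the highest ratios included Gpc3, a proteoglycan of growth factor signalling (265-fold), the imprinted Notch ligand relative Dlk1 (337-fold), the nuclear receptor Rora (23.05-fold) and the basement membrane collagen Col15a1 (88.1-fold). Ndufa4l2, a hypoxia-induced mitochondrial gene, was at 173 CPM in MPC with 0 UMIs in myoblast. That is 3154-fold higher against a floor of 3 counts, and 2565-fold at the lower end of the exact interval. The lowest ratios included the protease gene Mcpt8 (914-fold lower), the intracellular channel regulator Fgf13 (1.88 against 210.1 CPM) and the matrix cytokine Spp1 (15.5-fold lower, 7036 CPM in myoblast). The cultures also differed by 5 passages and in the whole medium, so the effect of the compounds alone was not measured. MPC cluster 7 (10.7% of cells) and the muscle differentiation-like cells lie outside the progenitor-like values.

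ASC against fiSC addresses activation after injury. Cell cycle, energy and early differentiation genes were higher in ASC, and quiescence, Notch, immediate early and matrix genes were lower, in all cells and in progenitor-like cells. Each of 20 G2/M genes was higher (median 3.22, progenitor-like 3.62), with Top2a at 292.6 against 5.86 CPM, as were 19 of 20 DNA replication genes (median 2.36). Of 17 oxidative phosphorylation genes 14 were higher (median 1.71), including Ndufa4 (9.53-fold), and of 13 glycolysis genes 9 were higher and 2 lower (median 1.72). Early differentiation genes were higher for 7 of 10 (median 1.49) and mature fibre genes for 4 of 6 (median 1.19), with the muscle enolase Eno3 at 423 against 3.45 CPM. Of 19 quiescence genes 16 were lower and 1 higher (median -3.12, progenitor-like -2.76), including Calcr (334-fold lower) and Spry1 (24.1-fold lower). Of 10 Notch genes 8 were lower (median -1.84), with Notch3 8.71-fold lower. All but 3 of the 19 immediate early and heat shock genes were lower (median -3.22), and Egr1 was at 37.4 against 3820 CPM. Genes of that list were among the leading genes of fiSC clusters 1 (Fos, Jun and Hspa1a) and 3 (Dnajb1 and Hspb1). What raised them in fiSC was not tested, so this difference need not come from activation. TGF-beta targets (9 lower, 2 higher of 11, median -2.88), cAMP/CREB targets (10 lower, 2 higher of 13, median -2.18), and extracellular matrix genes (16 lower of 19, median -2.35) were lower as well. Of 13 cholesterol synthesis genes 7 were lower (median -1.12), and of 8 imprinted growth genes 4 were lower (median -1.52). The p53 list had 5 of 9 higher (median 1.80), but 4 higher and 2 lower in progenitor-like cells (median 0.78). Interferon genes had a median of 1.05 in all cells and -0.88 in progenitor-like cells, and Bst2, an antiviral tether, was at 265 against 25.5 CPM in all cells.

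The 10 highest genes in ASC were macrophage transcripts or genes that macrophages share, such as the lysozyme Lyz2 (4175 against 3.104 CPM) and the complement gene C1qb (753 against 1.05 CPM). In the progenitor-like cells Lyz2 was at 91.1 against 0.105 CPM. Carry-over of RNA from the macrophage-like cells into the progenitor-like values of ASC was not tested, so this ratio need not be expression by progenitor-like cells. The lowest were genes of the fresh cells such as the peptide hormone Nppc (1068-fold lower), the matrix gene Hmcn2 (996-fold lower) and the dystrophin gene Dmd (100.4-fold lower). By the size rule 2290 genes were higher and 1960 lower, and 2159 and 2175 in progenitor-like cells (2482 and 2027 with TMM factors, 55.0% higher in place of 49.8%). With TMM factors, which moved the median of all genes from 0.08 to 0.33, the counts were 2859 and 1610 (64.0% higher in place of 53.9%). Macrophage-like cells made up 46.9% of ASC, and the libraries differ in muscle, animals, age and sex.

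MPC against ASC addresses how far the cultured progenitors resemble activated cells. Notch, quiescence, imprinted, matrix and hypoxia genes were higher in MPC in all cells and in progenitor-like cells, while most G2/M and DNA replication genes did not meet the size rule. Of 15 quiescence genes 10 were higher and 2 lower (median 2.01, progenitor-like 1.71), with Pax7 7.61-fold and Notch3 10.7-fold higher. Of 10 Notch genes 7 were higher (median 2.04, progenitor-like 2.51), with Hes1 11.9-fold and Heyl 27.1-fold higher. Each of 10 imprinted growth genes was higher (median 2.33, progenitor-like 2.43), including Cdkn1c (93.7-fold) and Peg3 (4.98-fold). Of 19 extracellular matrix genes 16 were higher and 1 lower (median 2.76), with the basement membrane collagen Col4a1 at 441 against 6.19 CPM. Hypoxia genes were higher for 7 of 10 (median 1.95) and glycolysis genes for 7 of 14 (median 1.14). Early differentiation genes had a median of 3.82 in all cells and 1.75 in progenitor-like cells, with the cardiac actin Actc1 at 193 against 0.359 CPM in the latter. In the muscle differentiation-like cells of MPC Actc1 was at 3615 CPM, and carry-over of their RNA into the progenitor-like values was not tested. Mature fibre genes had medians of 2.58 and 0.69, and myogenic transcription factors 1.03 and 1.10. The TGF-beta median was -1.12 (6 of 9 lower, 3 higher), with Pmepa1 2.25-fold lower. Of 20 G2/M genes 3 were higher (median 0.50, and 0.15 with TMM factors), Top2a 2.87-fold, Nusap1 2.58-fold and Aurkb 2.695-fold, and the summed list was at 3059 against 1949.7 CPM. Of 20 DNA replication genes 1 was higher (median -0.18), Mcm6 at 2.11-fold, while in progenitor-like cells 0 were higher and 1 lower. With TMM factors Nusap1, Aurkb and Mcm6 fell short of the size rule. Immediate early genes had a median of -1.52 in all cells but -0.32 in progenitor-like cells. The p53 list (0.49 and -0.36) and the cAMP/CREB list (-0.37 and 0.24) turned in sign between all and progenitor-like cells, and 8 of 9 interferon genes were lower (median -1.81), macrophage-like cells included.

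The lowest genes in MPC were the macrophage transcripts of ASC, such as Ctss (1.59 against 1486 CPM) and Apoe (25.2 against 5768 CPM). The highest included the sarcomere genes Actc1, Myl1 and Acta1, Cdkn1c, and the calcification inhibitor Mgp (845 against 10.2 CPM). By the size rule 1710 genes were higher and 1022 lower, and 1711 and 694 in progenitor-like cells. The TMM factors moved the median of all genes from 0.21 to -0.14 and the counts to 1126 and 1577 (41.7% higher in place of 62.6%), and in progenitor-like cells to 1059 and 1308 (44.7% in place of 71.1%). Without the macrophage-like cells (46.9% of ASC) the counts were 1665 and 547. Macrophage RNA carried over into the other ASC cells was not tested and could remain in the latter counts.

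MPC against fiSC addresses how far the cultured cells resemble freshly isolated ones. Each of 20 G2/M genes was higher in MPC (median 3.91, progenitor-like 4.33) and so were 17 of 19 DNA replication genes, while all 19 immediate early and heat shock genes were lower (median -4.26). The heat shock gene Hspa1a was at 0.894 against 4941 CPM. What raised the immediate early and heat shock genes in fiSC was not tested. The Notch list was near fiSC, with 1 of 10 higher and 1 lower (median 0.05, progenitor-like 0.35, and -0.06 with TMM factors), and Hes1 was 2.13-fold higher. Of 19 quiescence genes 10 were lower and 1 was higher (median -1.51, progenitor-like -1.38), including Calcr (1628-fold lower), Vcam1 (25.4-fold), Cd34 (212-fold) and the heparan sulphate proteoglycan Sdc4 (19.8-fold). Of 13 myogenic transcription factors 6 were lower and 3 higher (median -0.48), with Myf5 8.31-fold and Msc 20.8-fold lower. TGF-beta targets (8 of 11 lower, median -2.20), cAMP/CREB targets (9 of 13 lower, median -1.78) and interferon genes (5 of 7 lower, median -1.45) were lower, as were 6 of 14 cholesterol synthesis genes (median -0.93). Glycolysis (11 of 14, median 2.62), oxidative phosphorylation (15 of 17, median 1.51), hypoxia (6 of 10, median 1.64) and imprinted growth genes (6 of 10, median 1.31) were higher, with Egln3, an oxygen sensor, 30.02-fold higher. Early differentiation genes had a median of 5.11, and of 2.62 in progenitor-like cells. In MPC Myog was at 37.6 CPM in progenitor-like cells and at 1057 CPM in muscle differentiation-like cells (30.5% of the library). Whether RNA carried over from the latter adds to the progenitor-like values was not tested. The p53 list turned from 0.73 in all cells to -0.62 in progenitor-like cells. By the size rule 2704 genes were higher and 1536 lower, and 2793 and 1566 in progenitor-like cells. TMM factors gave 2132 and 1939 in the latter (52.4% higher in place of 64.1%). They moved the median of all genes from 0.35 to 0.23. Chodl, a satellite cell lectin, was at 0.797 against 415 CPM and Crabp1, a retinoic acid binding protein, at 382 against 0.0501 CPM (1 UMI), but at 12.0 CPM in the progenitor-like cells of MPC.

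Myoblast against fiSC addresses what culture without the compounds differed by. Of 19 quiescence genes 17 were lower in myoblast and 0 higher (median -3.41, progenitor-like -3.26), and 6 of 10 Notch genes were lower and 1 higher (median -1.36), with the ligand Jag1 14.3-fold lower. Msc, a repressor expressed in satellite cells, was at 0.128 against 390 CPM. Each of 20 G2/M genes was higher (median 3.47), as were 5 of 10 p53 genes (median 1.60), with Cdkn2a 116-fold and Ccng1 29.2-fold higher. Early differentiation (median 4.70, progenitor-like 2.596) and mature fibre genes (4.25 and 1.43) were higher, and Spp1 was at 7036 against 6.06 CPM. Carry-over of RNA from the muscle differentiation-like myoblast cells into the progenitor-like values was not tested. All 19 immediate early and heat shock genes were lower (median -4.66), hypoxia genes had a median of -1.73 and TGF-beta targets one of -1.80. The source of the high immediate early and heat shock levels in fiSC was not tested here either. By the size rule 2659 genes were higher and 1707 lower, and 2758 and 1648 in progenitor-like cells (2279 and 1951 with TMM factors, 53.9% higher in place of 62.6%). Myoblast against ASC gave 1360 higher and 893 lower (TMM 1005 and 1275, which is 44.1% higher in place of 60.4%), and in progenitor-like cells 1327 and 416 (TMM 856 and 865, 49.7% in place of 76.1%). TMM moved the median of all genes of that pair from 0.14 to -0.13.

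**Figure D3:**
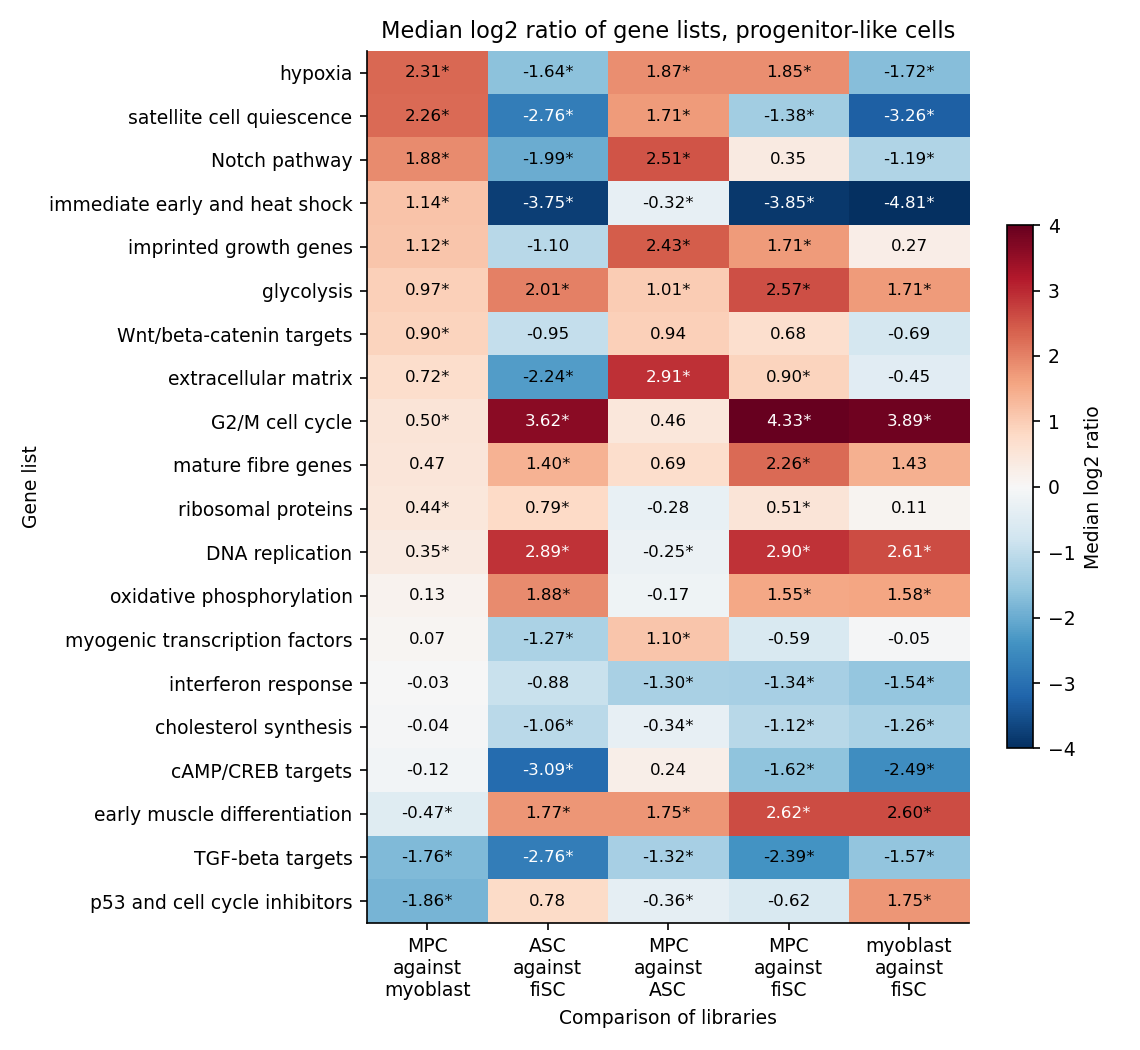
Median log2 ratio of each of the 20 gene lists in progenitor-like cells, coloured from lower (blue) to higher (red) in the first library, with a star where the median lay outside the central 95% of the matched random lists. The quiescence list is at 2.26 for MPC against myoblast and at -1.38 for MPC against fiSC, and in all cells the mature fibre list of MPC against myoblast was at -0.42 in place of 0.47.

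Across 10511 genes, which are not independent replicates, Pearson correlations of log2 levels were 0.889 for MPC and myoblast, 0.769 for myoblast and ASC, 0.737 for MPC and ASC, 0.659 for MPC and fiSC, 0.642 for ASC and fiSC, and 0.632 for myoblast and fiSC. The Spearman values were 0.862, 0.739, 0.700, 0.621, 0.6005 and 0.594. In progenitor-like cells the Pearson values were 0.842, 0.871, 0.817, 0.629, 0.633 and 0.605, so that myoblast and ASC were then the closest pair. Over all myogenic clusters MPC and myoblast were the closest, at 0.873 against 0.855 for myoblast and ASC. Of 1455 genes at least 4-fold apart between a random part of the myoblast cells and fiSC, 400 (27.5%) moved toward fiSC. That is, MPC differed at least 2-fold from the remaining myoblast cells in the direction of fiSC, genes past the fiSC level included. Another 56 (3.85%) lay at least 2-fold the other way, and 172 (11.8%) both moved toward fiSC and lay within 2-fold of it. In progenitor-like cells the toward share was 31.9%. Of 746 genes that far apart between myoblast and ASC, 192 (25.7%) moved toward ASC by that measure and 18 (2.41%) lay the other way. Both toward ASC and within 2-fold of it were 100 (13.4%). The toward share was 7.84% of the genes higher in ASC and 42.2% of those lower in ASC. In progenitor-like cells it was 176 of 358 (49.2%), and without macrophage-like cells 39.3%. Poisson draws of the myoblast profile, which hold counting error and no spread between libraries, gave 0% in each direction. If MPC ratios were independent of the in vivo library 6.24% would lie toward fiSC and 6.26% away. The myoblast library enters both sides of these shares, so an effect of that library alone also raises the toward share.

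**Figure D4:**
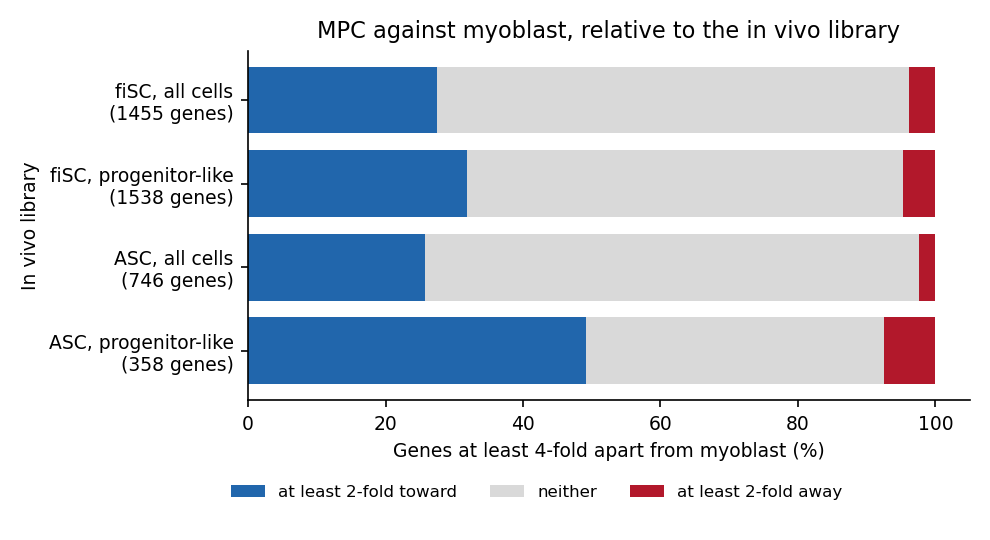
Percent of genes at least 4-fold apart between myoblast and fiSC or ASC whose MPC level lay at least 2-fold toward that library, at least 2-fold away, or neither (bars from 0). Toward fiSC it was 27.5% against 3.85% away, and toward ASC 25.7% against 2.41% away.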

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

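The tests of free RNA and of EGFP made by the macrophage-like cells, of the mix of classes and the scaling behind the quiescence genes, and of a single source of Pax7 were chosen only after the result was seen.

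A sequence for EGFP is among the features and belongs to none of the comparisons. It gave 64.6 CPM in fiSC, 24.1 in ASC, 179 in myoblast and 60.1 in MPC, above the limit that a count of 0 allows in each library. It drew attention as a signal in data that no comparison uses, and no control library without the reporter was analysed here. After thinning, EGFP was seen in 11.3% of fiSC, 3.46% of ASC, 30.4% of myoblast and 11.9% of MPC cells. Pax7 was also lowest in ASC, at 88.0 CPM, and highest in myoblast, at 1116 CPM. The EGFP intervals of MPC (58.8 to 61.4) and fiSC (61.2 to 68.3) overlap.

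Myogenic transcripts were also counted in the macrophage-like cells of ASC, which are 46.9% of a library sorted for GFP (28.8 to 48.1% in the other clusterings). Free RNA from the myogenic cells would bring each marker in 1 proportion, and 90.9% of the myogenic progenitor markers and EGFP (10 of 11) lay within 2-fold of the median, which was 3.97% of their level in the myogenic cells. The exception was Sdc4, at 84.8%. EGFP stood at 0.894 times that median (interval 0.680 to 1.16), which argues against EGFP RNA made by these cells. Free RNA may therefore account for these markers other than Sdc4, which alone gave 9776 of the UMIs and stays unexplained. Doublets with myogenic cells would also bring the markers in 1 proportion, and this test cannot tell them from free RNA. How these cells passed the GFP sort was not tested. The muscles were taken 3 days after cardiotoxin injury, and no biological explanation was tested.

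Most measured quiescence genes were higher in MPC than in myoblast, though Pax7 and Vcam1 were not. A different mix of cell classes would lower the median within progenitor-like cells, and it was 2.26 there against 2.00 in all cells. Scaling by total UMIs would lower it with TMM factors, and it was 1.91. The progenitor-like value argues against the mix of classes. The TMM factors were 1.04 for myoblast and 1.10 for MPC, too close to move the median far. The second value therefore shows only that TMM estimated a small difference in scaling. The biological difference named by the design, the medium with the compounds, stays open and untested, because it coincides with 5 further passages, the rest of the medium, the library and possibly the animal.

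Pax7 was counted in the fibroblast-like cells of MPC at 615 CPM, 66.9% of its level in progenitor-like cells. In the fibroblast-like clusters of the other libraries it was at 739 CPM in fiSC (60 cells), 2.19 in ASC (12 cells) and 22.6 in myoblast (32 cells), and the explanations were tested for MPC alone. The class depends on the clustering: it held 9.73% of MPC cells, and 4.19% at resolution 1.0, where Pax7 was not measured again. Transcripts brought in 1 proportion by free RNA or doublets would keep the markers together, and 75% of them (12 of 16) lay within 2-fold of the median, with Msc at 11.9% and Sdc4 at 181%. That share meets the bound set against this explanation with nothing to spare. It also counts Sdc4, whose level above that of the progenitor-like cells cannot come from such carry-over, so the share by itself decides nothing. Msc, Edn3 and Fgfr4, at 11.9, 12.5 and 16.5%, lay well below the 66.9% of Pax7. If the source resembles the mean progenitor-like cell, this argues against 1 proportion as the whole cause of Pax7 and not against a part. Progenitor-like cells grouped into this cluster would carry fewer fibroblast transcripts. Cells with a Pax7 UMI (486 of 877) held 0.576 times the fibroblast marker UMIs of those without (interval 0.507 to 0.654), between the bounds set for and against, so grouped cells cannot be told apart from fibroblast-like cells that express Pax7. No biological explanation was tested, since the design gives none.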

How the results depend on the processing

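The settings without macrophage-like cells, with all myogenic clusters, with MPC cluster 7 (led by Rgs5) and with TMM factors on progenitor-like cells were chosen only after the results were seen. No paired analysis was possible because each group is 1 library.

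The total of higher and lower genes by the size rule stayed within 1.5 times the main count in 84 of 96 cases. The others came from a pseudocount of 20 or a minimum of 50 CPM, which by construction pass fewer genes: 654 and 651 for MPC against myoblast, 2605 and 2490 for ASC against fiSC, 1421 and 1360 for MPC against ASC, 2393 and 2283 for MPC against fiSC, 2536 and 2452 for myoblast against fiSC, and 1216 and 1156 for myoblast against ASC. The counts in 1 direction moved further: lower genes in MPC against ASC numbered 1577 with TMM factors and 547 without macrophage-like cells in place of 1022, and in myoblast against ASC 416 in progenitor-like cells in place of 893.

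For the lists, 387 of 1080 values stayed within their counting interval, 684 moved and 9 reversed. A list counts as reversed only where its main median lay outside the central 95% of random lists, and other lists that turned in sign, such as interferon genes in ASC against fiSC (1.05 to -0.88 in progenitor-like cells), p53 genes in MPC against fiSC (0.73 to -0.62) and MPC against ASC (0.49 to -0.36), and cAMP/CREB targets in MPC against ASC (-0.37 to 0.24), are among those that moved. The mature fibre median of MPC against myoblast turned to 0.47 in progenitor-like cells, 0.51 with cluster 7 and 0.42 with TMM factors there. In myoblast against ASC, where it was positive, it was -0.23 with TMM factors in progenitor-like cells. The cAMP/CREB median of that pair turned to 0.38 in progenitor-like cells, 0.38 with cluster 7, 0.66 in all myogenic clusters, 0.63 without macrophage-like cells and 0.0316 with TMM factors in progenitor-like cells. Of 5320 values of named genes 2141 stayed, 3162 moved and 17 reversed. In progenitor-like cells Myh1 was at 0.0873 (MPC against myoblast). In ASC against fiSC, values in progenitor-like cells and without macrophage-like cells were -0.39 and -0.45 for Gdf15, -1.20 and -1.21 for Isg15, -0.24 and -0.19 for Irf7, and -0.33 and -0.41 for Oasl2. In MPC against ASC they were 0.48 and 0.79 for Rgs2 and 1.03 and 0.89 for Ier3, in progenitor-like cells -0.10 for Lef1, -2.30 for Ttn and -0.23 for Tnni2, and without macrophage-like cells 0.17 for Tgfbi (-0.08 in progenitor-like cells, not reversed). Where only progenitor-like cells or the removal of macrophage-like cells turned a value, the mix of cells is what the setting changes. Other causes were not tested.

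Class shares stayed within their interval in 49 of 90 cases. The progenitor-like share of ASC was 40.9% at resolution 0.2, 30.8% with doublets kept and 37.6% in joint clustering. That of myoblast was 70.5% at resolution 1.0 and 0% in joint clustering, where clusters followed the libraries and that of myoblast took another name. That of MPC was 52.5% at resolution 0.2, 33.3% at 1.0, 49.7% with all variable genes, 43.9% with doublets kept and 10.1% in joint clustering. The macrophage-like share of ASC was between 28.8 and 33.5% at resolution 1.0, with all variable genes and with doublets kept (the unnamed share was then 24.7 to 29.0%), the fibroblast-like share of MPC lay between 4.19 and 7.37% in the alternatives, and the muscle differentiation-like share of ASC was 0% at resolution 0.2 and 0.0155% in joint clustering. The fall of the macrophage-like share of ASC came with a like rise of its unnamed share, so it lay mostly in which clusters received a name. The cause of the other shifts was not tested.

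Cycling shares moved in 17 of 20 cases, and depth limits them. At 5000 UMIs, without thinning, in progenitor-like cells and with at least 4 UMIs they were 2.27, 5.13, 0.432 and 0.234% in fiSC, 55.4, 77.5, 86.2 and 29.3% in ASC, 58.3, 75.3, 54.7 and 33.4% in myoblast, and 70.2, 80.3, 67.0 and 46.4% in MPC, with 60.2% in MPC when doublets were kept. The fiSC share was the lowest in each of these settings. The order of the other libraries was not the same, since in progenitor-like cells ASC was the highest.

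The share toward fiSC was 15.5% at 2-fold, 31.9% in progenitor-like cells and 31.6% with cluster 7. Toward ASC it was 19.7% at 2-fold, 49.2% in progenitor-like cells, 41.1% in all myogenic clusters, 39.3% without macrophage-like cells and 48.3% with cluster 7. The value for all myogenic clusters also lacks the split of the myoblast cells. The toward share exceeded the away share in each of these. Correlations moved in 33 of 36 cases.

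Depth limits fiSC most, with a floor of 0.150 CPM, and only 470 myoblast cells pass the strict filter.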

Other observations

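The comparison in this part was added after the data were seen and was not among the planned ones, and it has no test.

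Muscle differentiation-like cells were also compared between MPC (2761 cells, clusters 4, 5, 6, 9 and 10) and myoblast (309 cells, clusters 2 and 9), with 1030 genes higher and 700 lower in MPC by the size rule. The class mixes unlike clusters. In MPC, cluster 4 (1520 of the 2761 cells) had summed differentiation markers of 8367 CPM and Mki67 at 192 CPM, and cluster 5 had 48291 and 13.7, while myoblast clusters 2 and 9 had markers of 81551 and 29491 CPM. The values therefore depend on where the class ends in each library and need not compare cells at the same stage. Of 21 early differentiation genes 14 were lower and 0 higher (median log2 ratio -1.32), and of 16 mature fibre genes 10 were lower and 2 higher (median -1.35). Mb, the oxygen store of fibres, was at 39.2 against 1290 CPM, the skeletal actin Acta1 at 2648 against 8696 CPM and Chrna1 at 187 against 1169 CPM. Myog was at 1057 against 1332 CPM. Cell cycle genes were higher, with 19 of 20 G2/M genes (median 2.55) and 14 of 18 DNA replication genes (median 1.63), and Mki67 was at 128 against 3.47 CPM. Hypoxia (8 of 9 higher, median 1.93) and Notch genes (5 of 8 higher and 1 lower, median 1.36) were higher and TGF-beta targets lower (6 of 7, 1 higher, median -2.19), as in progenitor-like cells. Of 11 quiescence genes 5 were higher and 1 lower (median 0.90). Cdkn1c was at 5191 against 126 CPM, above the 1384 CPM of progenitor-like MPC cells.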
